A study of Mus musculus with 6 samples.

How the data were processed

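RNA of mouse ovaries was sequenced in 6 libraries, 3 control and 3 FNZ, as poly(A) RNA with paired-end reads, per the labels. FNZ was injected at 30 mg/kg daily over 7 days, and the labels do not spell the name out or give a number of mice. Base calls were made with bcl2fastq 2.20 and the differential test with DESeq2 1.38.3 on the genome build GRCm39, per the submitters' processing notes. The aligner, the program that counted reads, the annotation release and the strand used in counting are not given in the sources used here.

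A single table was deposited. Its per-library count columns hold expected counts, as the authors deposited them, since 12.0% to 14.8% of the values per library are not whole numbers. The table also gives TPM per library, deposited by the authors and scaled for gene length to a sum of 1000000 per library. The authors' deposited log2 fold change, p-value and adjusted p-value come from DESeq2, per the submitters' processing notes, and their model is not given. A gene length in bases stands beside each gene, per the file headers, and how it was set is not stated. The 2 columns of group mean TPM were not used. Groups and replicate numbers follow the sample titles, whose numbers match the column names.

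The table lists 56980 genes, of which 24519 had 0 counts in all libraries. Total counts per library ran from 19333493 to 23406628. Counting error was used here only to set floors for genes with 0 counts in a group. It is not given separately for other values, since reads copied by PCR are not independent molecules.

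The test, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, genes kept by filterByExpr with the group, estimateDisp, glmQLFit with robust = TRUE and the two-sided quasi-likelihood F test), with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The plan was written for counts, and expected counts were treated in the same way. CPM values use the TMM-scaled library sizes, and errors are SDs over 3 libraries for CPM and SEs of the fit for log2 fold changes. The 33 gene lists (those of calcium channels and calcium handling, PI3K and AKT, mitochondria, metabolism, stress, ovarian cell types, immune cells, neighbouring tissues, blood and ribosomes) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, for lists of at least 3 tested members. Each list was also tested with a correlation estimated from the data, where 0 of the 33 lists passed (adjusted p from 0.893 to 0.981). That test rests on the residual degrees of freedom of so few libraries that it had little power. Granulosa genes (estimated correlation 0.05) and oxidative phosphorylation subunits (0.55) had the same adjusted p of 0.893. Failing it therefore does not show that a list was unshifted. Across the lists, 11 genes belong to more than 1 list.

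The text names the T-type channel genes, the 10 genes with the smallest edgeR p in each direction (used because no gene passed; at least 1 CPM on average, groups that do not overlap, and no predicted or clone name), and for called lists and those of the study's aim the 2 members with the smallest p. For lists that mark other tissues or RNA quality it names the 2 most abundant members. Some genes that the rule selects are not reported here. Genes given from the authors' table alone, and genes with counts in 1 group only, were chosen after their values were seen. Of 59 genes named by the rule, 18 share exon sequence with another gene on either strand in GENCODE M21 (GRCm38), 8 on the same strand and 12 on the opposite strand, and their counts are uncertain to that extent. Those on the same strand include Hspa8, Itpr3, Khdc3, Kctd12, Ovgp1, Rpl4 and Rps20, and those on the opposite strand Cacna1h, Ccn2, Itpr1, Tiparp and Vcam1. Mitochondrial genes were compared with annotated pseudogenes by shared 25-base words, and pairs sharing at least 80% were summed as an alternative. KEGG terms carried by the table, with 10 to 500 tested members, were tested only where a direction had at least 20 called genes.

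That first set held RLE and upper quartile scaling, DESeq2 1.42.0 with its defaults, limma voom, no filter, a filter of 1 CPM in 3 libraries, robust = FALSE, stricter and looser thresholds, replicate blocks, an estimated correlation and each library left out in turn. Alternatives chosen after seeing the data were a loess trend (span 0.3) of each library's log2 CPM on log2 gene length or on GC content as an offset in edgeR or DESeq2, this offset without FNZ replicate 3, limma with a trend on log2 TPM with a pseudocount of 1, DESeq2 on the filtered genes, and pooled mitochondrial copies. GC content was known for 98.1% of tested genes. The replicate block by title number compares replicates 2 and 3 alone, since control replicate 4 and FNZ replicate 5 have no partner of their number.

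The steps were tested on simulated data for FNZ against control, drawn from the measured means and library sizes of 17735 genes with 200 genes changed. edgeR recovered 56.7%, 86.6% and 100% of genes changed 2-fold, 4-fold and 8-fold, with 13 false calls, and DESeq2 64.2%, 85.1% and 97.0%, with 18 false calls. A simulated length trend (rho = -0.286) fell to rho = -0.0031 after the offset. Camera called a shifted list (adjusted p = 1.4e-13) and 0 of 40 unshifted lists. The draw used means, library sizes and the dispersion trend, and not each gene's own dispersion or the measured correlation between genes. It also held no library that deviates from its group as FNZ replicate 3 does. The recovered shares are therefore not the power of the measured comparison. Nor does the 0 give camera's rate of false calls where genes vary together. In the measured libraries, camera with the preset correlation called 11 lists between the groups, and 8 to 23 in other splits of the same libraries.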

Results

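RNA from mouse ovaries was measured in 6 libraries, 3 from control animals (replicates 2, 3 and 4) and 3 from animals given FNZ (replicates 2, 3 and 5). FNZ is the injected compound, which the labels give only by these letters, at a daily dose of 30 mg/kg into the peritoneum over 7 days. The deposited table gives expected counts per gene, which summed to 23406628, 22611517 and 22027408 in control replicates 2, 3 and 4 and to 19605103, 22587113 and 19333493 in FNZ replicates 2, 3 and 5. Between 25111 and 26343 genes had a count in a library. The labels mention 3 dissected ovaries per group but not whether they came from separate mice, so every p-value below measures the spread between these samples.

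The single comparison, FNZ against control, asks how a compound given to block T-type calcium channels alters ovarian transcripts, with mitochondria, follicles and PI3K/AKT signalling named in the title of the study. Nuclear-encoded subunits of oxidative phosphorylation and mitochondrially encoded transcripts lay higher in the FNZ libraries. Macrophage genes lay lower than in control replicates 2 and 4, and short genes as a whole had higher fold changes than long ones. edgeR's quasi-likelihood test called 0 of 17735 genes (0 higher, 0 lower) at a Benjamini-Hochberg adjusted p under 0.05, and its smallest adjusted p was 0.111. At an unadjusted p under 0.05 it had 4107 genes (2122 higher and 1985 lower with FNZ). In 5258 genes (29.6%) all FNZ libraries lay on the same side of all control libraries, where chance gives 10% on average over splits of the libraries. Genes vary together and the share was not computed for the other splits, so how far 1 split may exceed this average is not known. DESeq2 called 1497 genes (672 higher, 825 lower), limma voom called 2, and limma with a trend on TPM called 1. Without FNZ replicate 3, edgeR called 3230 genes (1464 higher, 1766 lower), whereas leaving out control replicate 3 or FNZ replicate 5 gave 1 gene each.

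Among the 10 genes with the smallest p on the higher side, Cnmd, which encodes the angiogenesis inhibitor chondromodulin, measured 49.0 ± 8.15 CPM (counts scaled by library size; SD, n = 3) in control and 137 ± 15.6 CPM (n = 3) in FNZ ovaries. Its log2 fold change was 1.48 ± 0.15 (SE) with an edgeR adjusted p of 0.111, and every FNZ library exceeded every control library, as the rule for naming these genes required. Fst, the activin-binding follistatin of granulosa cells, measured 276 ± 26.5 and 436 ± 15.2 CPM (log2 fold change 0.66 ± 0.11, edgeR adjusted p = 0.131). Acsbg1, a long-chain acyl-CoA synthetase, measured 549 ± 36.2 and 912 ± 94.8 CPM (log2 fold change 0.73 ± 0.12). The other higher genes of this set had log2 fold changes of 1.26 (Slfn4), 1.2 (Rnd2), 1.03 (Ppp1r14a, an inhibitor of myosin phosphatase), 1.02 (Exoc3l), 0.86 (Smarcd3, a chromatin remodelling subunit), 0.79 (Snapin) and 0.63 (Pcyt2, of phosphatidylethanolamine synthesis).

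On the lower side, Akr1c13, an aldo-keto reductase, measured 9.40 ± 2.32 CPM in control and 1.88 ± 0.221 CPM in FNZ ovaries (n = 3 each), a log2 fold change of -2.32 ± 0.27. Retnla, a product of alternatively activated macrophages, measured 2.68 ± 0.867 and 0.266 ± 0.0458 CPM (log2 fold change -3.31 ± 0.41). Tnfrsf1b, a receptor for tumour necrosis factor, measured 47.3 ± 5.13 and 22.4 ± 3.15 CPM (log2 fold change -1.08 ± 0.14). Ddx21, an RNA helicase of ribosome production, measured 167 ± 4.08 and 108 ± 8.10 CPM (log2 fold change -0.63 ± 0.10). The other lower genes had log2 fold changes of -1.13 (Celsr1, a cadherin of planar cell polarity), -1.09 (Olfml2a), -0.94 (Rassf8), -0.91 (Kctd12), -0.85 (Rc3h1, which promotes mRNA decay) and -0.76 (Phlpp2, a phosphatase that acts on AKT). All 20 genes were chosen among those whose groups did not overlap, and none passed edgeR's test, with adjusted p from 0.111 to 0.131. DESeq2 called 19 of the 20, all but Retnla, to which it gave no adjusted p, and edgeR called 20 when FNZ replicate 3 was left out. Exons of Exoc3l, Fst, Kctd12, Rnd2, Smarcd3 and Snapin overlap those of another annotated gene on the opposite strand, so their counts are uncertain.

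**Figure D1:**
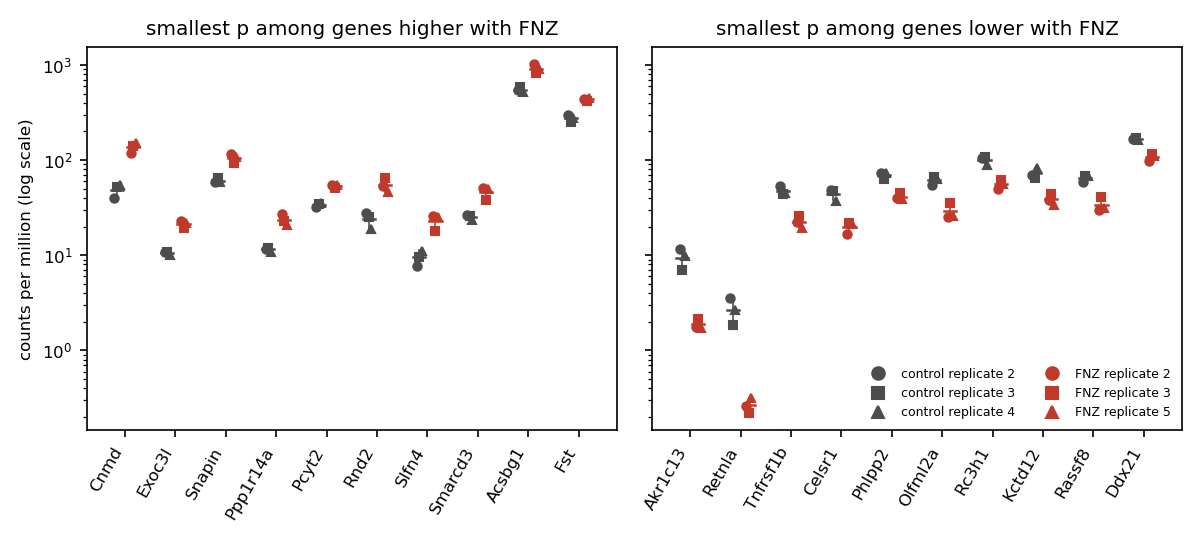
CPM (log scale) in each library for the 10 genes of smallest edgeR p on each side, with control in grey and FNZ in red, marker shape for the library, horizontal lines for group means and vertical lines for SD (n = 3). The 20 genes were chosen among those whose groups do not overlap, for example Cnmd at 49.0 against 137 CPM and Akr1c13 at 9.40 against 1.88 CPM.

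Of the T-type channel genes, Cacna1h (ENSMUSG00000024112) was the most abundant, at 42.8 ± 7.32 CPM in control and 41.5 ± 7.26 CPM in FNZ ovaries (n = 3 each). Its log2 fold change of -0.04 ± 0.17 (edgeR adjusted p = 0.902) was smaller than the spread between replicates and became 0.00052 with upper quartile scaling and 0.25 with a correction for gene length. Exons of Tpsg1 lie opposite those of Cacna1h, and the strand used in counting is not given in the sources used here. Cacna1g (ENSMUSG00000020866) measured 4.68 ± 1.81 and 2.47 ± 0.509 CPM (log2 fold change -0.92 ± 0.37, edgeR adjusted p = 0.194), with control replicate 3 at 2.59 CPM inside the FNZ range. Cacna1i (ENSMUSG00000022416) measured 0.697 ± 0.12 and 0.405 ± 0.243 CPM (log2 fold change -0.79 ± 0.50, edgeR adjusted p = 0.369), and its log2 fold change was -1.36 without FNZ replicate 2 and -0.49 without FNZ replicate 3. As a list, the 3 genes were not called by camera (adjusted p = 0.233), and 0 passed when adjusted over the list alone or by DESeq2, which gave Cacna1i no adjusted p.

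**Figure D2:**
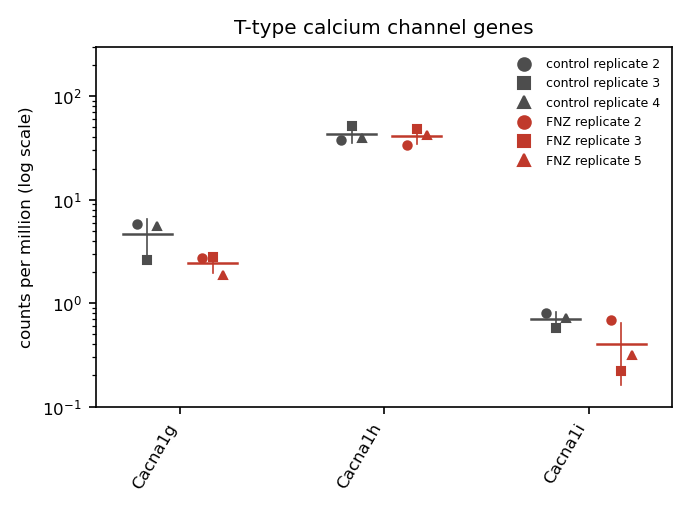
CPM (log scale) of the T-type channel genes Cacna1g, Cacna1h and Cacna1i in each control (grey) and FNZ (red) library, with group means as horizontal and SDs as vertical lines (n = 3). Cacna1h lies near 42.8 CPM in control and 41.5 CPM in FNZ ovaries, and Cacna1g and Cacna1i overlap between groups.

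Intracellular calcium genes were called lower by camera with the preset correlation (46 members, 31 negative, median log2 fold change -0.16, adjusted p = 0.0408; adjusted p = 0.893 with an estimated correlation). Of these, 0 members passed edgeR over all genes or adjusted over the list alone (8 lower and 1 higher over all genes without FNZ replicate 3, or 0 with the length correction), and camera's adjusted p was 0.200 after the correction for gene length. The median was -0.25 without FNZ replicate 3 and -0.10 without FNZ replicate 2, and the call was lost without FNZ replicate 2 or 5 or control replicate 4 (camera adjusted p = 0.0809, 0.102 and 0.0636). It was also lost with the 1 CPM filter (camera adjusted p = 0.0784) and the replicate block by title number (0.148). Itpr3 and Itpr1, which encode inositol trisphosphate receptors that release calcium from the endoplasmic reticulum, had log2 fold changes of -0.69 ± 0.16 and -0.53 ± 0.16 (edgeR adjusted p = 0.131 and 0.138). With the correction for gene length these were -0.36 and -0.22 (edgeR adjusted p = 0.311 and 0.408). The other voltage-gated channel subunits were not called (14 tested, 9 negative, camera adjusted p = 0.815).

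Nuclear-encoded oxidative phosphorylation subunits had the smallest camera p of the 33 lists. Of 79 members, 73 had a positive log2 fold change, with a median of 0.45 and a camera adjusted p of 6.1e-15 (adjusted p = 0.893 with an estimated correlation). Adjusted over the list alone, 59 members rose and 0 fell, against 0 over all genes tested with edgeR, and in 64 members every FNZ library exceeded every control library. Without FNZ replicate 3, 55 rose and 1 fell over all genes tested with edgeR, or 6 and 0 with a correction for gene length. Ndufs4 and Ndufa8, subunits of complex I, measured 60.4 ± 4.66 against 106 ± 21.4 CPM and 51.2 ± 2.37 against 80.5 ± 11.5 CPM (log2 fold changes 0.81 ± 0.16 and 0.65 ± 0.12, edgeR adjusted p = 0.131 for each). These are short genes, with a median length of 765 bases against 2705 for all tested genes. With a correction for gene length the median was 0.22, camera's adjusted p was 4.5e-07, and 13 members rose adjusted over the list alone. The list's median deviation from the mean of all libraries was 0.47 in FNZ replicate 2, 0.17 in FNZ replicate 5 and 0.02 in FNZ replicate 3, against -0.17 to -0.32 in the controls.

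Mitochondrially encoded proteins were also called higher (13 members, 12 positive, median log2 fold change 0.54, camera adjusted p = 0.00176; adjusted p = 0.893 with an estimated correlation). Adjusted over the list alone 6 members rose, against 0 over all genes tested with edgeR, or 9 over all genes without FNZ replicate 3 (4 with the correction for gene length). Single-gene values are uncertain, because 7 pseudogenes at 24611535 to 24616197 of chromosome 1 (GRCm38) carry nearly the same sequence and held 98.7% of the combined counts for mt-Co2 and 86.5% for mt-Nd3. Unpooled, mt-Co2 and mt-Nd3 had log2 fold changes of 1.17 ± 0.21 and 1.54 ± 0.37 (edgeR adjusted p = 0.131 each), and pooled with their copies 0.49 ± 0.18 and 0.72 ± 0.25 (edgeR adjusted p = 0.169 and 0.16). With all copies pooled, 8 of 13 members rose adjusted over the list alone, and the median was 0.54, or 0.28 after the correction for gene length. Together these transcripts and copies took 3.53% ± 0.216 of counts in control and 4.92% ± 1.02 in FNZ ovaries (SD, n = 3 each), higher in 3 of 3 FNZ libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

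**Figure D3:**
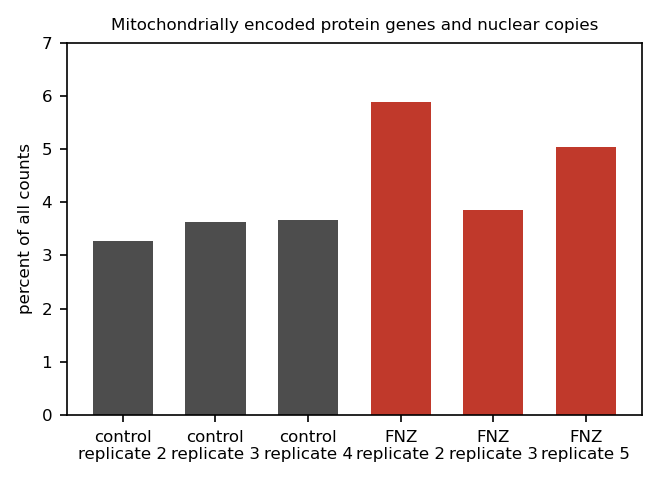
Percent of all counts on mitochondrially encoded protein genes and their chromosome 1 copies, with a bar for each control (grey) and FNZ (red) library. Control bars lie from 3.28% to 3.67% and FNZ bars at 5.88%, 3.85% and 5.03% for replicates 2, 3 and 5.

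Other energy and stress lists moved less. Mitochondrial biogenesis, dynamics and mitophagy was not called (38 members, 21 positive, median 0.05 and mean -0.0044, camera adjusted p = 0.920; 0 higher and 1 lower adjusted over the list alone, 0 over all genes with edgeR). Glycolysis (24 tested gene records, 15 positive) and fatty acid oxidation and lipid storage (27 members, 16 negative) had camera adjusted p of 0.255 and 0.958, with 2 members of each higher adjusted over the list alone. Antioxidant defence was called higher (36 members, 26 positive, median log2 fold change 0.20, camera adjusted p = 0.0408; adjusted p = 0.893 with an estimated correlation). Adjusted over the list alone 4 members rose and 1 fell, against 0 over all genes with edgeR. Its call was lost after the correction for gene length (camera adjusted p = 0.629) and without control replicate 3 or 4 or FNZ replicate 2 (camera adjusted p = 0.0647, 0.106 and 0.0999). Gpx8 and Gstm2, a peroxidase and a glutathione transferase, had log2 fold changes of 0.72 ± 0.13 and 0.51 ± 0.11 (edgeR adjusted p = 0.131 each). Cytosolic ribosomal proteins were called higher (49 members, 45 positive, median 0.40, camera adjusted p = 1.3e-06; adjusted p = 0.893 with an estimated correlation). With edgeR 0 members passed adjusted over the list alone, and after the correction for gene length the median was 0.17 (camera adjusted p = 0.037). Without FNZ replicate 2 the median was 0.25. Without FNZ replicate 3, edgeR called 34 ribosomal members higher and 1 lower over all genes, or 1 each with the length correction, and 8 antioxidant members higher and 3 lower, or 0 and 2. Rps20 had a log2 fold change of 0.82 ± 0.23 (edgeR adjusted p = 0.134). The abundant Rpl4 and Rplp0 had log2 fold changes of 0.15 ± 0.12 and -0.03 ± 0.11, the latter turning to 0.02 with upper quartile scaling.

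PI3K and AKT signalling was called lower by camera (59 members, 44 negative, median log2 fold change -0.20, adjusted p = 0.00297; adjusted p = 0.893 with an estimated correlation). Adjusted over the list alone 1 member fell, Phlpp2, against 0 over all genes tested with edgeR. Without FNZ replicate 3, edgeR called 18 members lower and 3 higher over all genes, or 2 and 1 with the correction for gene length. Phlpp2, which removes an activating phosphate from AKT, ranged from 63.1 to 73.9 CPM in control and from 39.3 to 44.7 CPM in FNZ ovaries (log2 fold change -0.76 ± 0.11, edgeR adjusted p = 0.131). Pdpk1, the kinase that activates AKT, measured 69.6 ± 1.28 and 46.8 ± 8.12 CPM (log2 fold change -0.57 ± 0.13, edgeR adjusted p = 0.131). The list holds long genes (median 5012 bases), and with a correction for gene length its median was 0.03 and camera's adjusted p 0.527.

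**Figure D4:**
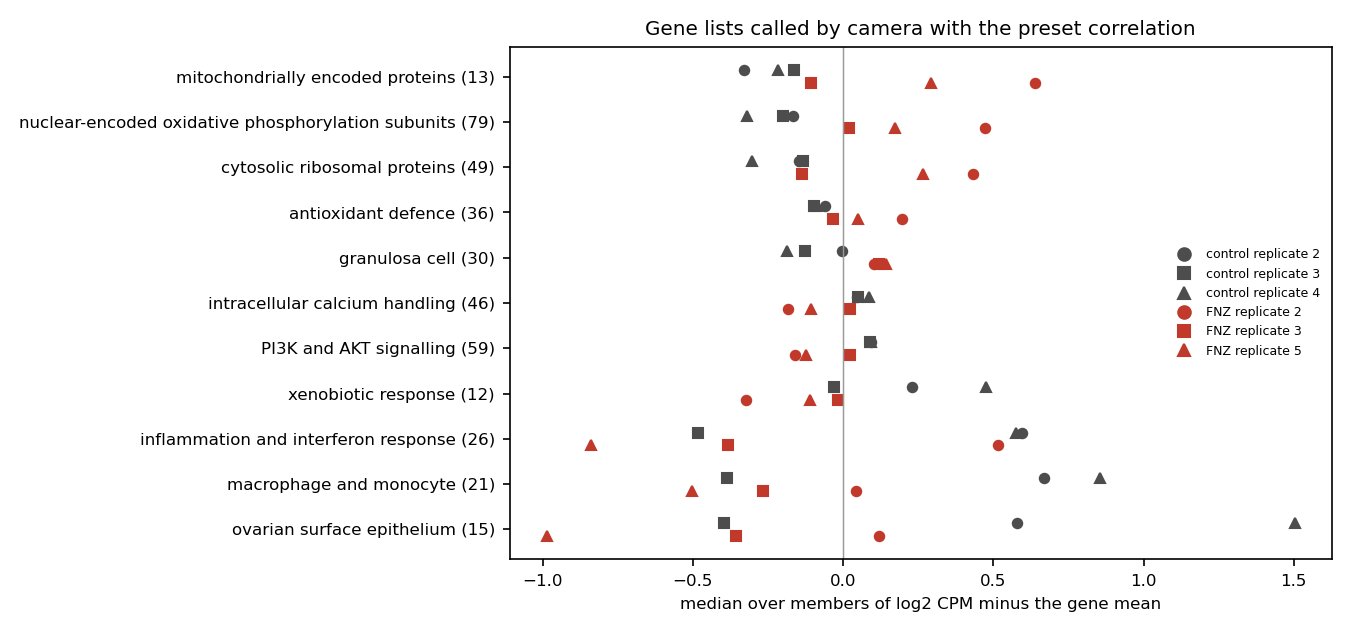
Median over the members of each called list of log2 CPM minus the gene's mean over the 6 libraries, for control (grey) and FNZ (red) libraries, with the number of tested members in brackets. The oxidative phosphorylation list separates the groups (FNZ replicate 3 at 0.02, controls at -0.17 or lower), whereas in the macrophage list control replicate 3 (-0.39) lies among the FNZ libraries.

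Gene length marked the libraries themselves. Across the 17735 tested genes, which are not independent replicates, the log2 fold change was negatively correlated with gene length (Spearman's rho = -0.42), from a median of 0.37 in the shortest decile to -0.28 in the longest. Within libraries, the deviation from the gene's mean correlated with length at rho = 0.26 to 0.32 in the controls, -0.46 in FNZ replicate 2, -0.30 in FNZ replicate 5 and 0.08 in FNZ replicate 3. Genes that DESeq2 called higher had a median length of 1429 bases and those called lower 5310 bases. The 18S ribosomal RNA gene Rn18s-rs5 took 0.522%, 0.393% and 0.34% of counts in FNZ replicates 2, 3 and 5 and 0.307%, 0.293% and 0.322% in control replicates 2, 3 and 4. The 10 most abundant genes took 7.15%, 5.45% and 6.36% of counts in these FNZ libraries and 4.89%, 5.06% and 5.09% in the controls, so both shares were higher in every FNZ library. With a correction for length, added after seeing the data, edgeR called 2 genes and DESeq2 630.

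**Figure D5:**
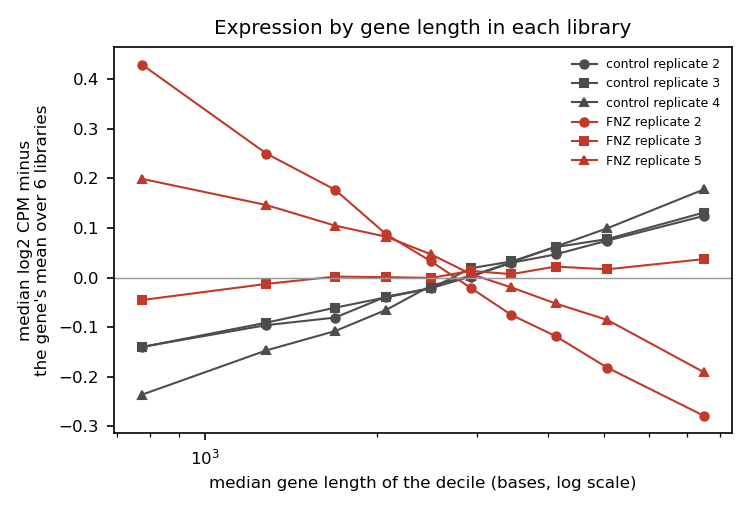
Median log2 CPM minus the gene's mean over the 6 libraries (vertical axis) against the median gene length of each decile of the tested genes (log scale), with a line for each control (grey) and FNZ (red) library. In the shortest decile FNZ replicates 2 and 5 lie at 0.43 and 0.20, FNZ replicate 3 at -0.05 and the controls at -0.14 to -0.24.

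In follicle cells, granulosa genes were called higher (30 members, 22 positive, median log2 fold change 0.19, camera adjusted p = 0.0371; adjusted p = 0.893 with an estimated correlation). Adjusted over the list alone 3 members rose, against 0 over all genes tested with edgeR (7 without FNZ replicate 3, or 2 with the length correction), and 5 rose and 1 fell after the correction for gene length, with a median of 0.20. The median was 0.30 without control replicate 2 or FNZ replicate 2, and the call was lost without FNZ replicate 3 (median 0.13, camera adjusted p = 0.102) or control replicate 4 (camera adjusted p = 0.176). Beside Fst, Hsd17b1, which converts estrone to estradiol, measured 202 ± 27.2 and 305 ± 17.3 CPM (log2 fold change 0.60 ± 0.13, edgeR adjusted p = 0.131). Theca and steroidogenesis genes were not called as a list (18 tested, 9 positive, camera adjusted p = 0.958 toward higher values, with a median of -0.06), although 3 rose adjusted over the list alone and 0 over all genes tested with edgeR. Hsd3b1, which acts in progesterone synthesis, measured 1973 ± 400.1 and 3585 ± 329.6 CPM (log2 fold change 0.86 ± 0.17, edgeR adjusted p = 0.131). Fdxr, which passes electrons to mitochondrial steroid enzymes, measured 85.2 ± 11.3 and 139.6 ± 6.91 CPM (log2 fold change 0.71 ± 0.12, edgeR adjusted p = 0.131).

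Oocyte genes were not called (37 members, 31 positive, median log2 fold change 0.24, camera adjusted p = 0.255), with 0 adjusted over the list alone by edgeR and 0 in the authors' deposited table. Oog1 and Khdc3, both expressed in oocytes, had log2 fold changes of -0.47 ± 0.21 and 0.52 ± 0.31 (edgeR adjusted p = 0.239 and 0.348). The oocyte list's median deviation ran from -0.51 in FNZ replicate 3 to 0.59 in FNZ replicate 5, and control replicate 3 stood at 0.31, so it varied within both groups. Camera called the list higher without FNZ replicate 3 (adjusted p = 0.000362), without control replicate 3 (adjusted p = 0.00547) and with FNZ replicate 3 out and the correction for gene length (adjusted p = 0.0155). It called the list lower with the replicate number of the titles as a block (adjusted p = 0.0152), which compares replicates 2 and 3 alone. The direction of the oocyte list was not settled. Corpus luteum (12 tested, 8 negative, camera adjusted p = 0.255), ovulation and cumulus expansion (17 tested, 9 negative, 0.456), cholesterol synthesis and uptake (26 tested, 18 positive, 0.456) and the cell cycle (40 tested, 26 positive, 0.263) were not called. Corpus luteum genes were called lower without FNZ replicate 3 (camera adjusted p = 0.0179, or 0.0131 with the length correction), and cholesterol genes higher without FNZ replicate 2 (0.0175). Theca genes were called lower with FNZ replicate 3 out and the length correction (0.0391).

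Macrophage and monocyte genes were called lower (21 members, 20 negative, median log2 fold change -0.65, camera adjusted p = 0.00176; adjusted p = 0.893 with an estimated correlation). Adjusted over the list alone 2 members fell, against 0 over all genes tested with edgeR (1 without FNZ replicate 3, or 0 with the length correction). In 4 members every FNZ library lay below every control library (19.0%, where 29.6% of all tested genes had groups that did not overlap). Adgre1, which encodes the macrophage surface protein F4/80, measured 21.4 ± 9.23 and 7.44 ± 1.57 CPM (log2 fold change -1.53 ± 0.35, edgeR adjusted p = 0.131). The scavenger receptor Cd163 measured 9.74 ± 4.38 and 2.43 ± 1.13 CPM (log2 fold change -2.0 ± 0.49, edgeR adjusted p = 0.131). The list's median deviation was 0.67 and 0.85 in control replicates 2 and 4 but -0.39 in control replicate 3, below FNZ replicates 2 (0.04) and 3 (-0.27) and above FNZ replicate 5 (-0.50). Inflammation and interferon response was called lower as well (26 tested, 21 negative, median -0.55, camera adjusted p = 0.0408; adjusted p = 0.934 with an estimated correlation). With edgeR 0 of these members passed adjusted over the list alone. The list's median deviations were 0.59, -0.48 and 0.58 in control replicates 2, 3 and 4 and 0.52, -0.38 and -0.84 in FNZ replicates 2, 3 and 5, so control replicate 3 lay below FNZ replicates 2 and 3. The median was -0.94 without FNZ replicate 2, and the call was lost without FNZ replicate 3 (-0.33, camera adjusted p = 0.226), FNZ replicate 5 (-0.31, 0.519), control replicate 2 (-0.44, 0.168) or control replicate 4 (-0.37, 0.365). It was also lost with RLE scaling (camera adjusted p = 0.0526) and the 1 CPM filter (0.0513), and with the replicate block by title number the camera direction turned higher (0.958). Vcam1, an adhesion molecule, and Tnfaip3, an inhibitor of NF-kB signalling, had log2 fold changes of -1.10 ± 0.30 and -0.64 ± 0.24 (edgeR adjusted p = 0.133 and 0.175). Lymphocyte and granulocyte genes were not called (18 tested, 15 negative, median -0.72, camera adjusted p = 0.141). They were called lower after the correction for gene length (median -0.90, camera adjusted p = 0.0203, or 0.901 with an estimated correlation as well). The same call came with the block by library name number (camera adjusted p = 0.0464) and without control replicate 3 (0.0157) or FNZ replicate 2 (0.00563).

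Markers of tissue around the ovary also differed between libraries. Adipocyte genes (12 tested, 10 negative, camera adjusted p = 0.255) had median deviations of 1.52 in control replicate 4, 1.30 in FNZ replicate 3 and 0.48 in control replicate 2, beside -1.05 and -1.49 in control replicate 3 and FNZ replicate 5. Car3 and Lpl, both abundant in fat, measured 637 and 285 CPM in control replicate 4 and 15.4 and 116 CPM in FNZ replicate 5. The adipocyte list was called lower without control replicate 3 (camera adjusted p = 0.00908) or FNZ replicate 3 (0.0476, or 0.00387 with the length correction). Oviduct genes (15 tested, 13 negative, camera adjusted p = 0.505) deviated by 1.80 in control replicate 4 and 0.89 in FNZ replicate 2, and by -0.61 to -1.08 in the other libraries. The oviduct list was called lower without control replicate 3 (camera adjusted p = 0.0469) and higher with the title block (7.4e-07). The title block drops control replicate 4, the library with the highest oviduct median, from the contrast. The oviduct glycoprotein Ovgp1 reached 555 CPM in control replicate 4 and 13.3 CPM in FNZ replicate 2, against 2.19 to 6.81 CPM elsewhere, and Tppp3 34.5 and 32.3 CPM in these libraries, against 12.2 to 21.7 CPM. Ovarian surface epithelium was called lower (15 members, 14 negative, median log2 fold change -1.0, camera adjusted p = 0.0361; adjusted p = 0.934 with an estimated correlation). Its median deviations were 0.58, -0.40 and 1.5 in control replicates 2, 3 and 4 and 0.12, -0.36 and -0.99 in FNZ replicates 2, 3 and 5. This is the same order of the 6 libraries as for the macrophage list. With edgeR 0 members passed adjusted over the list alone. The median was -0.43 without control replicate 4 (camera adjusted p = 0.192), and the call was also lost without control replicate 2 or FNZ replicate 3 or 5 (camera adjusted p = 0.0686, 0.113 and 0.143). Lrrn4 and Gpm6a of that list had log2 fold changes of -1.67 ± 0.53 and -0.91 ± 0.31 (edgeR adjusted p = 0.145 and 0.159). Without control replicate 4, 5 lists were called in place of 11, and the calls for surface epithelium, inflammation, xenobiotic response, intracellular calcium, antioxidant defence and granulosa cells were lost. The same 6 calls were lost with the replicate block by title number. That block also drops control replicate 4 from the contrast, so it is not a separate test of these calls. The calls for antioxidant defence and xenobiotic response were also lost with the block by library name number (camera adjusted p = 0.062 and 0.069).

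Xenobiotic response genes were called lower (12 tested, 10 negative, median log2 fold change -0.35, camera adjusted p = 0.0371; adjusted p = 0.893 with an estimated correlation). With edgeR 0 members passed adjusted over the list alone, and camera's adjusted p was 0.113 after the correction for gene length. The call was also lost without control replicate 4 (median -0.21, camera adjusted p = 0.176) and without FNZ replicate 2 or 3 (camera adjusted p = 0.057 and 0.092). Tiparp, a target of the aryl hydrocarbon receptor, and the transporter Abcc1 had log2 fold changes of -0.51 ± 0.13 and -0.38 ± 0.13 (edgeR adjusted p = 0.132 and 0.148). With the correction for gene length these were -0.38 and -0.13 (edgeR adjusted p = 0.206 and 0.542). Lists not called were stroma and extracellular matrix (30 members, 18 negative, camera adjusted p = 0.519, with 3 higher and 2 lower adjusted over the list alone), endothelial (19 members, 13 negative, 0.228), smooth muscle and pericyte (15 members, 11 positive, 0.337) and erythroid (6 tested, 3 negative, 0.614). Hbb-bs and Hba-a1, the most abundant erythroid genes, had log2 fold changes of -0.41 ± 0.66 and 0.26 ± 0.44. Also not called were apoptosis and p53 targets (29 tested, 17 negative, 0.456, with a median of -0.04 and a mean of 0.0034), endoplasmic reticulum stress (26 tested, 16 negative, 0.309), heat shock (13 members, 9 negative, 0.158) and immediate early response (23 members, 16 negative, 0.0786). The immediate early list was called lower after the correction for gene length (camera adjusted p = 0.0115, or 0.0458 with FNZ replicate 3 out as well). With that correction and an estimated correlation its camera adjusted p was 0.901. It was also called lower without control replicate 2 or 3 or FNZ replicate 2 (camera adjusted p = 0.011, 0.0118 and 0.0114). Endothelial genes were called lower without control replicate 3 (camera adjusted p = 0.00547), smooth muscle genes higher without FNZ replicate 5 (0.00434) and with the title block (0.000755), and erythroid genes lower with the length correction and FNZ replicate 3 out (0.00832). Hsp90ab1 and Hspa8, heat shock genes, had log2 fold changes of -0.19 ± 0.11 and 0.11 ± 0.13, and the immediate early genes Ccn2 and Myc -0.17 ± 0.21 and 0.20 ± 0.20.

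The authors' deposited table held 1484 genes with an adjusted p under 0.05, 662 higher and 822 lower with FNZ, of which 1483 were also called by the DESeq2 run made here. It marks 227 genes as significant (92 higher, 135 lower), which are those with an absolute log2 fold change of at least 1 as well. Its genes with an adjusted p under 0.05 were ranked where they averaged at least 1 CPM and their groups did not overlap, predicted genes aside. Among these, the largest rises included Fggy (log2 fold change 3.29, adjusted p = 0.00293), Rpgrip1 (2.78, adjusted p = 0.00151) and the theca hormone gene Insl3 (2.46, adjusted p = 0.0025). Fggy rested on FNZ replicate 3, at 17.5 CPM against 2.72 and 1.62 CPM in the other FNZ libraries. Rpgrip1 rested largely on FNZ replicate 2, at 16.0 CPM against 1.87 and 6.58 CPM in the other FNZ libraries, and Insl3 shares exon sequence with Jak3 on the same strand. The largest falls among the same genes in the authors' deposited table were Star (log2 fold change -2.88, adjusted p = 0.0421), which carries cholesterol into mitochondria, and the growth factor gene Fgf1 (-2.81, adjusted p = 2.36e-06). Ovgp1 (-4.76) and Retnla (-3.37) fell further there but were not called, and the DESeq2 run made here gave neither gene an adjusted p. Star stood at 588 CPM in control replicate 4, against 70.1 and 94.3 CPM in the other controls and 18.6 to 52.2 CPM in FNZ ovaries. Among the lists, 31 nuclear-encoded oxidative phosphorylation genes and 7 granulosa genes rose in the authors' deposited table, while 5 macrophage genes and 4 PI3K and AKT genes, among them Phlpp2, Pdgfra and Pdpk1, fell.

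Pathway terms could not be tested on edgeR's calls, of which there were 0. Among genes called by DESeq2, 12 KEGG terms were over-represented on the higher side and 0 on the lower side (one-sided Fisher's exact test, Benjamini-Hochberg over 644 tests). Oxidative phosphorylation led with 43 of its 118 tested members (adjusted p = 5.2e-26), followed by Thermogenesis with 46 of 203 (adjusted p = 2.1e-18). Fisher's test treats genes as independent, whereas the oxidative phosphorylation list had an estimated correlation of 0.55, so these p-values may be too small. Terms may share members and are not separate results. Of DESeq2's higher calls 82.3% were shorter than the median tested gene, against 13.0% of its lower calls. Ribosome (18 of 127 members, adjusted p = 0.000794) had an adjusted p of 1 once gene length was in the model, and PPAR signaling pathway (9 of 55 members, adjusted p = 0.0382) had 0.0175.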

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

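The alternatives with gene length, GC content, TPM, DESeq2 on filtered genes, and DESeq2 terms with other sizes, backgrounds or a length spline were chosen after seeing the data. edgeR's count of 0 called genes (4107 at an unadjusted p under 0.05) remained 0 with RLE and upper quartile scaling, the 1 CPM filter, robust = FALSE, an adjusted p under 0.1 and the added fold threshold. It was 183 without a low-count filter (99 higher, 84 lower, of 32252 tested), 1497 with DESeq2 (672 higher, 825 lower), 1706 with DESeq2 on the filtered genes (786 higher, 920 lower), 2 with limma voom (1 higher, 1 lower), 2 with the gene length offset (1 higher, 1 lower), 630 with that offset in DESeq2 (395 higher, 235 lower), 2 with the GC offset (1 higher, 1 lower) and 1 with TPM (1 higher, 0 lower); the cause was not tested. Leaving out 1 library at a time gave 0 to 3230 genes (0 to 1464 higher, 0 to 1766 lower), with 3230 without FNZ replicate 3 and 653 (312 higher, 341 lower) when the length offset was added. Of the genes called by DESeq2, 1281 were also called by edgeR without FNZ replicate 3 and 486 by DESeq2 with the length offset. All 20 genes of smallest p kept their direction in every alternative, which their choice among genes with groups that do not overlap largely fixed in advance. Of 59 named genes, these included, 47 did.

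The replicate block by title number gave 24 genes (19 higher, 5 lower), and the replicate block by library name number gave 2 (2 higher, 0 lower). Libraries of the same number did not deviate together from their group means (r = -0.08 for number 2, r = -0.14 for number 3), nor did the remaining pair by library name (r = -0.32), and not every library correlated best with its own number. No pairing by number was seen. Deviations within a group of 3 libraries sum to 0, so these values cannot exclude a shared litter, day or batch. With the title block 8 lists were called, of which 5 were among the 11 and the oocyte (lower, adjusted p = 0.0152), smooth muscle (higher, 0.000755) and oviduct (higher, 7.4e-07) lists were not, and the calcium handling, antioxidant, granulosa, inflammation, surface epithelium and xenobiotic calls were lost. With the library name block 10 lists were called, the antioxidant and xenobiotic calls were lost, and the lymphocyte and granulocyte list was gained as lower.

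The 11 called lists were 10 with RLE (inflammation lost), 9 with the 1 CPM filter (inflammation and calcium handling lost), 9 with the length offset (7 of them shared, the lymphocyte and immediate early lists gained as lower), 12 with the length offset and FNZ replicate 3 out, 5 to 16 with 1 library left out (5 without control replicate 4, 16 without control replicate 3), 0 with an estimated correlation and 0 with the length offset and an estimated correlation. The oxidative phosphorylation, mitochondrially encoded, ribosomal, macrophage and PI3K and AKT lists were called with each of the 6 libraries left out, the granulosa list in 4, the calcium handling, antioxidant and xenobiotic lists in 3, and the inflammation and surface epithelium lists in 2. The PI3K and AKT median of -0.20 turned to 0.035 with the length offset (also with an estimated correlation) and to 0.0091 when FNZ replicate 3 was left out too; the offset removes the trend of long genes by construction.

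Cacna1h turned from -0.04 to 0.00052 with upper quartile scaling, 0.25 with the length offset in edgeR and in DESeq2, 0.22 with that offset and FNZ replicate 3 out, and 0.053 with TPM, and ran from -0.17 to 0.11 with 1 library left out, while Cacna1i ran from -1.36 to -0.49 and Cacna1g from -1.21 to -0.73. With the title block the log2 fold changes of Car3, Lpl, Ovgp1, Tppp3, Hbb-bs and Ccn2 turned to 0.68, 0.29, 1.07, 0.30, 0.072 and 0.19, since that block compares replicates 2 and 3 alone and drops control replicate 4 and FNZ replicate 5 from the contrast. With 1 library left out, Lpl ran from -0.70 to 0.12, Ovgp1 from -5.60 to 0.63, Tppp3 from -0.67 to 0.071, Ccn2 from -0.33 to 0.12, Hba-a1 from -0.29 to 0.58 and Rplp0 from -0.10 to 0.041. Rplp0 was 0.017 with upper quartile scaling, and Hba-a1 -0.68 with the length offset and FNZ replicate 3 out. With TPM, Hba-a1, Myc, Hspa8 and Rpl4 turned to -0.11, -0.0495, -0.23 and -0.10. TPM was used without TMM scaling, and at an unadjusted p under 0.05 its fit had 700 genes higher and 3841 lower. The main edgeR fit had 2122 and 1985, so these turns are not particular to the 4 genes. The cause was not tested.

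Pathway terms were not run on edgeR's calls, nor were their alternatives of term size and background, since no gene was called. DESeq2's calls gave 12 terms, also with terms of 5 to 1000 members and with all tested genes as background, and 11 with a spline of gene length (9 higher, 2 lower). The share of counts on mitochondrial proteins and copies differed by 0.912 to 1.93 percentage points with 1 library left out. Alternatives of pseudocount and low-value filter, planned for a table without counts, did not apply. With 19333493 to 23406628 counts per library, genes under 1 CPM had few counts, which limits Cacna1i and Retnla.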

Other observations

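Tests of the length-matched lists, of surface epithelium as a covariate and of the gene length count without FNZ replicate 3, and the exchange of that library with the controls, were chosen after the results they measure were seen. Beyond the lists, DESeq2's higher calls included 9 of 55 tested genes of the PPAR signaling term (one-sided Fisher's exact test, adjusted p = 0.0382). The authors' deposited table also gave Fabp3, a fatty acid carrier, a log2 fold change of 1.19 (adjusted p = 0.00138), and Ppara, a receptor for fatty acids, one of -1.60 (adjusted p = 0.00759). In the same list Hadh, of fatty acid oxidation, had 0.40 (adjusted p = 0.0102) in the authors' deposited table. Gapdh and Eno1, of glycolysis, had 0.73 (adjusted p = 0.00189) and 0.66 (adjusted p = 0.00959) there, and edgeR's adjusted p was 0.131 for each of the 2 genes. Pfkfb3, of the same glycolysis list, had -0.58 (adjusted p = 0.0417) in the authors' deposited table.

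Predicted genes with counts in every library of 1 group and 0 in the other were chosen after their values were seen. Gm49388 had 234, 206 and 127 counts in the controls and 0 in FNZ, at least 56.4-fold lower against a floor of 3 counts per library, and its exons overlap Setd1a and Hsd3b7 on the same strand. Gm44267 and Gm47924 had 0 counts in the controls and were at least 27.9-fold and 19.6-fold higher with FNZ. These folds scale counts by each library's total without the TMM factors, and are lower bounds on that scale only. No explanation was tested for these genes.

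With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 0 edgeR genes (highest other 5, and 10 of the 10 splits gave as many), 11 lists (highest other 23, and 7 splits gave as many) and 1497 DESeq2 genes (highest other 380, and 1 split gave as many). The split with 23 lists set control replicates 2 and 4 and FNZ replicate 3 against the rest, the libraries with the highest adipocyte medians, which points to a structure of the samples beside the groups.

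The first pattern was the negative relation of fold change to gene length. A difference in RNA integrity or fragment length between libraries predicts it in every kind of gene, and rho was below -0.2 in 20 of 21 functional categories of at least 100 genes. With rho = -0.42 over all tested genes, and with categories that share genes, this count was likely whatever the cause. It therefore does not tell such a technical difference from an effect of FNZ that acts by transcript length. Both stay open, since no RNA integrity values are given. Among 10000 random lists matched on length and expression, 1 had a median as high as the oxidative phosphorylation list, 83 as high as the mitochondrially encoded list, 34 as high as the granulosa list and 0 as low as the macrophage list. The random lists held genes drawn independently, whereas members of these lists may vary together (estimated correlation 0.55, 0.68, 0.05 and 0.56 in that order). The counts therefore cannot exclude length combined with variation between samples. With the length offset and an estimated correlation no list passed (smallest camera adjusted p = 0.901), but that test had little power with so few libraries. For the ribosomal (1373), PI3K and AKT (1041) and calcium handling (875) lists, length could account for the whole shift.

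The second pattern was that FNZ replicate 3 lay nearer the controls. On 1813 genes that part FNZ replicates 2 and 5 from the controls after the length offset, its median position was 0.337 (0 for the control mean, 1 for the mean of FNZ replicates 2 and 5). Each other library was scored on its own genes, those that part the rest of its group from the other group. Control replicates 2, 3 and 4 took 0.217, 0.447 and 0.157 (643, 898 and 646 genes), and FNZ replicates 2 and 5 took 1.05 and 0.932. There the FNZ mean included FNZ replicate 3. These positions share neither genes nor scale with 0.337, so they do not rank FNZ replicate 3 among the controls. A control library under the FNZ label may explain the low position of FNZ replicate 3, and an FNZ animal that responded less stays open, as untested. Counted against a wrong label, exchanging this library with control replicate 2, 3 or 4 gave 12, 380 and 62 DESeq2 genes in place of 1497, where 4 exchangeable controls would give like counts, but the highest of 4 arrangements falls on the labelled one by chance too often to exclude it. The length trend as the whole cause was argued against, because 653 genes were called without this library and 2 with it after the length offset.

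The third pattern was the lower macrophage list. With the adipocyte median as a covariate the list remained lower (median log2 difference from -0.61 to -0.51, camera adjusted p = 0.00203). The same held for the oviduct median (median -0.55, camera adjusted p = 0.00304). These tissue medians thus took up little of the shift. Carried adipose or oviduct tissue is not excluded, since camera with the preset correlation called up to 23 lists in other splits. A median over 12 or 15 genes may also miss part of a tissue's share. Surface epithelium carried along and fewer macrophages cannot be told apart, since the medians of both lists followed the same order of the 6 libraries, so that the loss of the call with the surface epithelium median as a covariate (median -0.054, camera adjusted p = 0.474) decides nothing. Control replicate 3, at -0.39, lay below FNZ replicates 2 and 3, so a difference between animals in ovarian macrophages may contribute beside FNZ, which was not tested. The call did not hold with an estimated correlation (camera adjusted p = 0.893), a test with little power in so few libraries, so this does not decide against it.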
